A study of Mus musculus and Canis lupus familiaris and Equus caballus with 9 samples.

How the data were processed

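NRSF (also called REST) is a zinc-finger repressor that binds a long DNA element near neuronal genes and is known for keeping those genes silent outside neurons. It was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse RAW264.7 macrophages, dog ML2 myelomonocytic leukaemia cells and horse E.Derm skin fibroblasts, all established cell lines. Each species had 2 immunoprecipitated samples and 1 input DNA sample. Per the labels, cells were fixed with 1% formaldehyde, and the libraries were selected for fragments of 200 to 300 bp. The mouse and dog cells were at passages 13 to 15 and the horse cells at passage 10.

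The deposited data used here are 4 peak lists, for mouse, dog, horse and human. The values the authors deposited are positions, not signal: each line gives a chromosome, a start and an end, with no score, fold enrichment or p-value for a peak and no value per replicate. Every peak is 400 bp wide in each list, and every start is a multiple of 5. The submitters' processing notes name Bowtie 0.12.8 (a read aligner) and MACS 1.4.2 (a peak caller), with no further role, and the builds GRCh37 (hg19), GRCm38 (mm10) and CanFam3.1. The horse build, the peak threshold and the way the 2 replicates were combined are not given in the sources used here. The labels tie 1 list to both immunoprecipitated samples of a species. No sample label concerns human cells, so the cells behind the human list are not given in the sources used here. Whether positions count from 0 or from 1 is not stated, which leaves 1 base of uncertainty. The lists hold no read counts, so the depth of each library is unknown, and neither the threshold nor the depth can be set equal between species.

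Gene positions came from a RefSeq table of GRCm38.p6, the assembly that mm10 also denotes, and were used with the mouse list only. The table gives the start and end of a gene but neither its strand nor its exons. Transcription start sites could therefore not be placed, and the tests planned on them were run on both annotated gene ends and on the gene span. A gene was counted as having a peak when the midpoint of a peak lay inside its span or within 10 kb of either end. A peak near several genes counts for each of them. Control windows were the peaks moved by 50 kb, or by 200 kb in the alternative and for the gene lists.

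Before the data were examined, 12 gene lists were fixed: 9 neuronal lists and 3 control lists of myeloid markers, fibroblast markers and ribosomal or housekeeping genes. The neuronal lists were drawn up from general knowledge with the known role of NRSF in mind and did not leave out genes already reported as its targets, so their excess is not independent of that knowledge. Of the 336 entries of all 12 lists, 333 matched a gene of the table, 3 of these through a synonym. In all, 319 list places went to protein-coding genes, which were the ones tested. Each list was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 12 lists. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. Genes were named by a rule also fixed before the data were examined: with no peak score, the 3 members of each list with a peak closest to an annotated gene end, the gene of NRSF itself, and up to 3 members of each control list. The rule as fixed measured distance to a transcription start site, for which the closer gene end stood in. Other genes named were chosen after their values were seen.

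The number of mouse peaks per chromosome was compared with the share of annotated length, taken up to the last annotated gene, by exact binomial tests. Peak spacing was compared in all 4 lists with 1000 random placements that kept the chromosome of each peak and ran from its first to its last peak. The smallest p-value these placements can give is 0.001. Bins of 1 Mb with 10 or more peaks are called dense bins. The alternatives were other reaches, protein-coding genes only, control windows moved further, and, added after the data were seen, leaving out the dense bins, comparing with random gene lists matched on gene length (by decile of length, or by drawing each member from the 50 genes nearest to it in length), other reaches for microRNA genes, and using named genes only as the background. The gene tests and the placement test were tested on simulated data for the mouse comparison with 21900 genes. All 200 genes given a planted peak were recovered, 100 of 100 lists of 30 genes with 15 planted members passed, and 10 of 500 random lists passed. The planted peaks lay within the 10 kb reach, so their recovery checks the counting only. The random peaks were placed evenly and the random lists drawn without regard to gene length. The 10 of 500 therefore do not cover clustered peaks or lists of long genes. Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3 was used.

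No genome sequence was used here, so the planned searches for the binding motif, its spacing variants and base composition were not run. Target genes of dog, horse and human peaks were not analysed here because no annotation of their builds was used. Each species has 1 list, so differences between species were described and not tested: they compare lists, which also differ in cell type, species and possibly depth.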

Results

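The data comprised 9 ChIP-seq samples, 6 from NRSF immunoprecipitation and 3 from input DNA, and 4 lists of NRSF peaks. The series title places the comparison between species around the evolution of the NRSF binding element. The mouse list held 2357 peaks, the dog list 2273 and the horse list 2185. The human list, which belongs to none of the 9 samples, held 5260 peaks and was 2.23 times as long as the mouse list. With a width of 400 bp for each peak, the lists covered 943 kb in mouse, 909 kb in dog, 874 kb in horse and 2104 kb in human. No peaks overlapped within a list. There was 1 list per species and no value per replicate, so replicate error could not be given for any value, the read depth is unknown, and all intervals cover counting error only.

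The gene content of the mouse list addressed which genes lay at NRSF peaks in a macrophage line. Genes of neuronal function, in lists that did not leave out genes already reported as NRSF targets, carried peaks more often than other genes. Of the 229 protein-coding genes in the 9 neuronal lists together, 126 had a peak (55.0%, 95% interval 48.3 to 61.6%), compared with 1514 of the 21671 other protein-coding genes (6.99%). The odds ratio was 16.3 (95% interval 12.4 to 21.5; Fisher's exact test, p = 1.39e-80). The 126 genes lay beside 163 distinct peaks, and 31 of them had more than 1 peak. In 97 of the 126 genes a peak lay inside the gene span, and in 50 a peak lay within 1 kb of an annotated end. Of the 9 neuronal lists, 8 passed the test after adjustment, and none of the 3 control lists did, with or without adjustment.

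**Figure D1:**
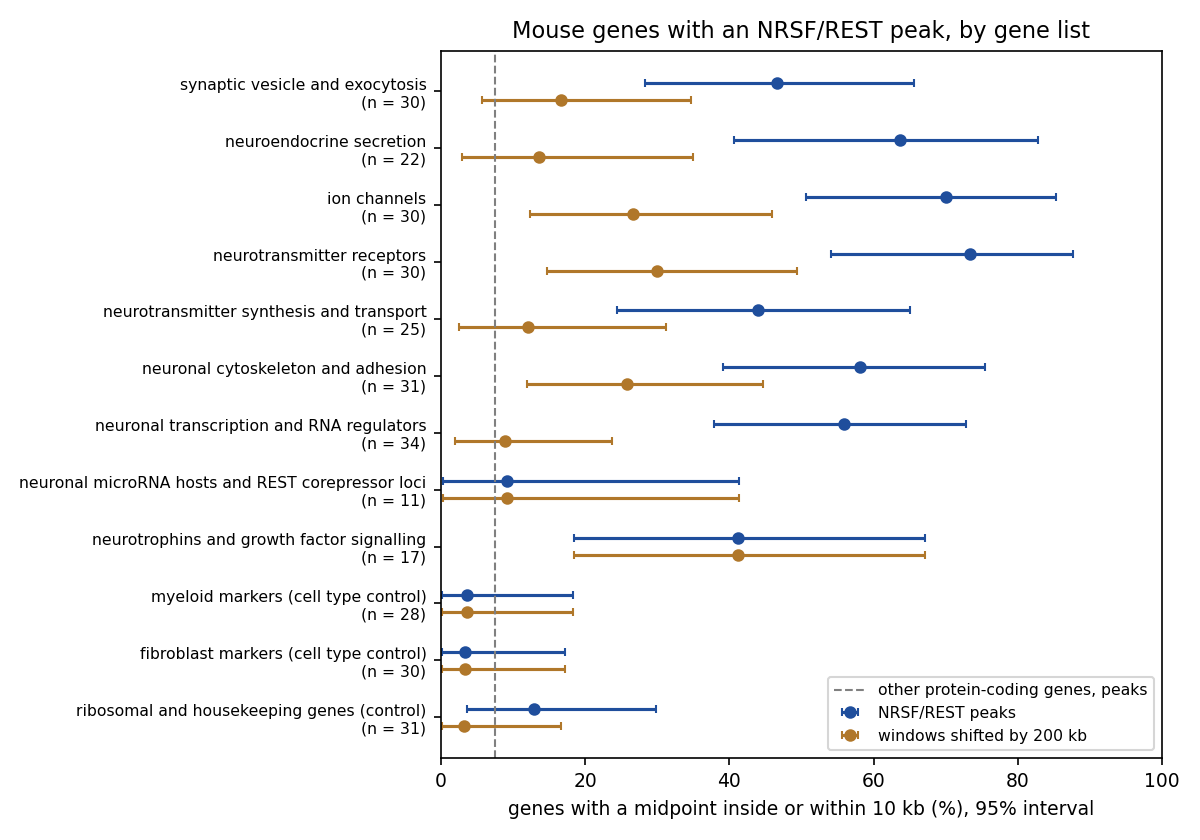
Share of mouse genes in each list with a peak midpoint inside or within 10 kb of the gene, in percent, with exact 95% intervals, where blue points are NRSF peaks, brown points are the same windows moved by 200 kb, and the dashed line is the share of other protein-coding genes with a peak. The list of neurotransmitter receptors reached 73.3% with peaks and 30.0% with moved windows, whereas the list of neurotrophins and growth factor signalling stood at 41.2% with both.

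Neurotransmitter receptors had the highest share of the 12 lists when gene spans counted, with a peak at 22 of 30 genes (73.3%, odds ratio 34.4, Fisher's exact test with Benjamini-Hochberg adjustment, adjusted p = 5.91e-18). The members with a peak closest to a gene end were Grin1, the obligatory subunit of NMDA-type glutamate receptors, Chrnb2, a nicotinic acetylcholine receptor subunit, and Grm2, a metabotropic glutamate receptor. The Grin1 peak lay on chromosome 2 at 25318825 to 25319225 (mm10), with its midpoint inside the gene and 162 bp from its end. The midpoint was 167 bp inside an end of Chrnb2 and 226 bp outside an end of Grm2. With gene spans counted, ion channels followed the receptors with 21 of 30 genes (70.0%, odds ratio 29.2, adjusted exact p = 9.08e-17). With only gene ends within 10 kb, 14 of 30 ion channel genes had a peak (46.7%, odds ratio 14.8). The order at the top also changed there: neuroendocrine secretion stood highest with 59.1%, against 56.7% for the receptors. Within 1 kb of an end it was again highest, with 9 of 22 genes against 12 of 30 receptor genes. When each peak went to its nearest gene end, the receptors stayed highest (73.3%). Cacng2, an auxiliary subunit that regulates AMPA-type glutamate receptors, had 4 peaks, the closest at 78119685 to 78120085 on chromosome 15. Scn3b, a sodium channel beta subunit, and Kcnc1, a voltage-gated potassium channel, had peaks 539 and 626 bp inside a gene end.

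Genes of neuroendocrine secretion carried peaks at 14 of 22 members (63.6%, odds ratio 21.8, adjusted exact p = 7.16e-11). The granins Scg2 and Chgb, which are packed into dense-core secretory granules, and Nppa, the precursor of atrial natriuretic peptide, had peaks within 9, 163 and 1 bp of an annotated end. The Nppa peak lay on chromosome 4 at 148001875 to 148002275. In the list of synaptic vesicle and exocytosis genes, 14 of 30 had a peak (46.7%, odds ratio 10.9, adjusted exact p = 1.53e-08). Syp, which encodes the vesicle protein synaptophysin, had a peak on chromosome X at 7638555 to 7638955, across the lower end of its annotated span. Syn1, encoding synapsin I, had a peak 217 bp outside an end, and Unc13a, a vesicle priming factor, had one 29 bp inside. In the list of neurotransmitter synthesis and transport, 11 of 25 genes had a peak (44.0%, odds ratio 9.76, adjusted exact p = 1.15e-06). Tph2, the brain enzyme of serotonin synthesis, Slc17a6, a vesicular glutamate transporter, and Slc18a1, a vesicular monoamine transporter, had peaks 17, 45 and 663 bp inside an end. Chat and Slc18a3, whose span lies within that of Chat, shared 1 peak, as did the neighbours Ptprn and Resp18.

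Neuronal cytoskeleton and adhesion genes had a peak at 18 of 31 members (58.1%, odds ratio 17.3, adjusted exact p = 1.21e-12). Examples were Cdk5r1, the activator of the neuronal kinase CDK5, with a peak 42 bp inside an end, Stmn3, a microtubule regulator, with one 285 bp inside, and Mapk8ip2, a kinase scaffold, with one 406 bp outside. Neuronal transcription and RNA regulators had a peak at 19 of 34 members (55.9%, odds ratio 15.8, adjusted exact p = 9.27e-13). Lhx3 and Pou4f3, homeodomain factors of neuronal differentiation, had peaks 26 and 202 bp outside an end, and Neurod4, a proneural factor, had one 39 bp inside. The list of neurotrophins and growth factor signalling had a peak at 7 of 17 genes (41.2%, odds ratio 8.68, adjusted exact p = 0.000195). Its closest members were Bdnf, encoding a neurotrophin, with a peak at 109675855 to 109676255 on chromosome 2, 1355 bp inside an end, Nrg2, with a peak 8333 bp outside an end, and L1cam, a neural adhesion molecule, with a peak 11303 bp inside an end. This last list did not pass when only gene ends within 10 kb or within 1 kb counted. Within 10 kb of an end, 2 of 17 genes had a peak (odds ratio 2.24, Fisher's exact test, adjusted p = 0.33, with a range of 0.000181 to 1 over the alternatives run). It did pass when each peak went to its nearest gene end at any distance (6 of 17 genes, odds ratio 5.9, Fisher's exact test, adjusted p = 0.00303).

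The ninth neuronal list joined NRSF, its corepressors and microRNAs, not all of them specific to neurons. Of its 11 protein-coding genes 1 had a peak, a share that did not differ from that of other genes in the test (odds ratio 1.24, 95% interval 0.0285 to 8.69, Fisher's exact test, adjusted p = 0.69). That gene was Rest itself, which encodes NRSF and had 2 peaks, the closest on chromosome 5 at 77265665 to 77266065 and 371 bp inside an annotated end. Of the list's 11 microRNA genes matched, 9 had a peak within 10 kb, compared with 44 of the 1217 other microRNA genes (3.62%, odds ratio 118, 95% interval 23.5 to 1153, Fisher's exact test, p = 1.34e-11), in a test chosen after the data were seen. These microRNAs include ones already reported as NRSF targets, so the excess is not independent of how the list was chosen. Of the 9, 5 lay 5122 to 9505 bp from their closest peak, and within 5 kb 4 of the 11 had a peak, compared with 21 of the others (odds ratio 32.1, exact p = 4.02e-05). Windows moved by 200 kb met none of the 11 within 10 kb. Mir124a-3, from the brain-enriched miR-124 family, had a peak 438 bp away, whereas Mir124a-2 had its closest peak 1898865 bp away. Mir132 and Mir212, which lie side by side, shared the peak at 75173345 to 75173745 on chromosome 11.

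None of the control lists differed in the test from other protein-coding genes, of which 7.48 to 7.49% had a peak. All peaks tested here came from the mouse macrophage line, so fibroblast markers were not examined at peaks of a fibroblast line. Of 28 myeloid markers 1 had a peak, the integrin gene Itgam, with the peak 2255 bp outside its span (odds ratio 0.457, 95% interval 0.0112 to 2.78, Fisher's exact test, adjusted p = 0.724). Of 30 fibroblast markers 1 had a peak, the fibulin gene Fbln2 (odds ratio 0.426, adjusted exact p = 0.724; the odds ratio was 1.2 when each peak went to its nearest gene end). Of 31 ribosomal and housekeeping genes 4 had a peak, namely Eef1a1, Rpl11, Rps3 and Rpl5, the last named after its value was seen (odds ratio 1.83, adjusted exact p = 0.385). The Eef1a1 peak lay 337 bp, the Rpl11 peak 1001 bp and the Rps3 peak 1084 bp inside an annotated end. With this number of members, an odds ratio of up to 2.57 for fibroblast markers and up to 5.27 for ribosomal and housekeeping genes lay within the intervals.

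The same lists were counted with windows moved by 200 kb to give the background. In genes longer than 200 kb a moved window can stay inside the same gene, so this background can count a peak again. Together the 9 neuronal lists then had 47 of 229 genes with a window (20.5%, odds ratio 3.41, 95% interval 2.41 to 4.75). Of the 9 lists, 4 passed Fisher's exact test with the moved windows, against 8 with the peaks, so that passing it was not by itself beyond background. These were neurotrophins and growth factor signalling (odds ratio 9.09), neurotransmitter receptors (5.57), ion channels (4.72) and cytoskeleton and adhesion (4.52), with adjusted exact p from 0.00106 to 0.00367. In an exact sign test over genes, chosen after the data were seen, 96 neuronal genes had a peak and no moved window and 17 the reverse (p = 1.47e-14). By list, that test passed after adjustment for 4 lists, namely ion channels, neurotransmitter receptors, neuroendocrine secretion and neuronal transcription and RNA regulators. It gave an adjusted exact p = 0.0539 for synaptic vesicle genes, 0.0618 for cytoskeleton and adhesion and 0.0661 for neurotransmitter synthesis and transport. The list of neurotrophins and growth factor signalling had 7 genes with a peak and 7 with a moved window.

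Mouse peaks lay close to gene ends more often than control windows did. Of the 2357 peaks, 448 had their midpoint within 1 kb of an annotated gene end (19%, 95% interval 17.4 to 20.7%), compared with 195 of the windows moved by 50 kb (8.27%; odds ratio 2.6, Fisher's exact test, p = 2.81e-27). Within 5 kb the shares were 41.6% and 31.0% (odds ratio 1.59, exact p = 3.39e-14). The shares inside a gene span, 59.3% of peaks and 58.3% of windows, did not differ in the test (odds ratio 1.04, 95% interval 0.926 to 1.17, exact p = 0.515, and 0.959 with protein-coding genes only). A window moved by 50 kb can stay inside a longer gene, so this comparison cannot exclude a preference for gene spans. These tests did not use the pairing of each window with its peak. In all, 1521 peaks (64.5%) lay inside or within 10 kb of a protein-coding gene, and 504 had no annotated gene of any kind within that reach.

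Peaks were unevenly spread over the mouse chromosomes. Against annotated length, 5 of the 21 chromosomes held more peaks and 6 held fewer (exact binomial tests, adjusted over chromosomes). Chromosome 7 had 216 peaks, 1.72 times the number expected, and chromosomes 4 and 11 had 1.62 and 1.61 times. Chromosomes 5 and 15, also above their share, had 1.36 and 1.245 times. Chromosome X, which carries Syp, Syn1 and L1cam, had 55 peaks, 0.372 times the number expected (adjusted exact p = 9.91e-18). When the number of protein-coding genes set the expectation, 5 chromosomes were off their share, with 4, 5 and 15 above it and 17 and X below it. Chromosomes 5, 15 and 17 had 1.31, 1.34 and 0.745 times the number expected from genes. Chromosome 4 then stood at 1.54 times (adjusted exact p = 1.2e-08) and X at 0.529 times (adjusted exact p = 1.28e-06), whereas chromosomes 7 and 11 stood at 0.988 and 0.981 times, and Y went from 0.381 to 1.09 times. Chromosome copy number and read mappability were not examined, so the X and Y ratios cannot be read as a difference in binding. On chromosome 4, 65 of the 220 peaks lay between 145 and 148 Mb, and without the peaks in dense bins its ratio to annotated length fell to 1.19 (adjusted exact p = 0.0635).

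**Figure D2:**
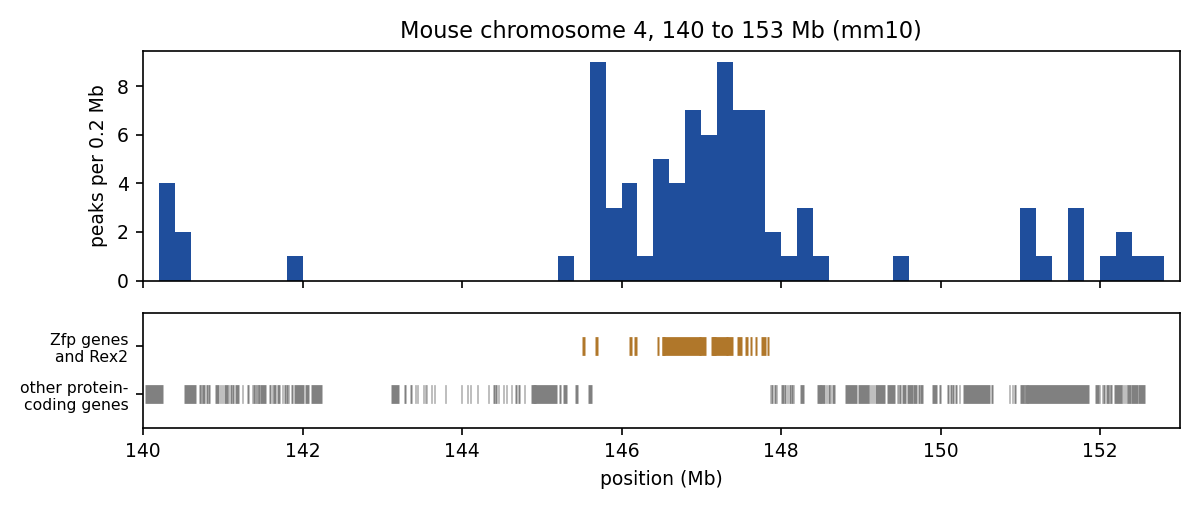
Mouse peaks per 0.2 Mb along chromosome 4 from 140 to 153 Mb (upper panel) above the spans of protein-coding genes (lower panel), with Zfp genes and Rex2 in brown and other genes in grey. The block of 65 peaks between 145 and 148 Mb lies where the Zfp genes are.

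The spacing of peaks could be compared in all 4 species, since it needs positions only. In each list, peaks had a neighbour within 10 kb more often than random placements did. The placements were even along the chromosome and took no account of genes or assembly gaps. A list concentrated near genes could pass this test for that reason alone. The share was 10.7% in mouse, 13.9% in dog, 16.8% in horse and 29.6% in human, against 2.01%, 2.28%, 2.19% and 4.04% at random (permutation p = 0.001 in each list, one-sided, the smallest that 1000 placements can give). Within 2 kb the human list stood at 24.0% (95% interval 22.8 to 25.1%), compared with 4.62% in mouse, 6.82% in dog and 6.59% in horse. Of the distances between consecutive starts, 10.1% in human and 1.71 to 2.37% in the other lists were at most 1 kb. These shares describe the lists and were not tested between species.

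**Figure D3:**
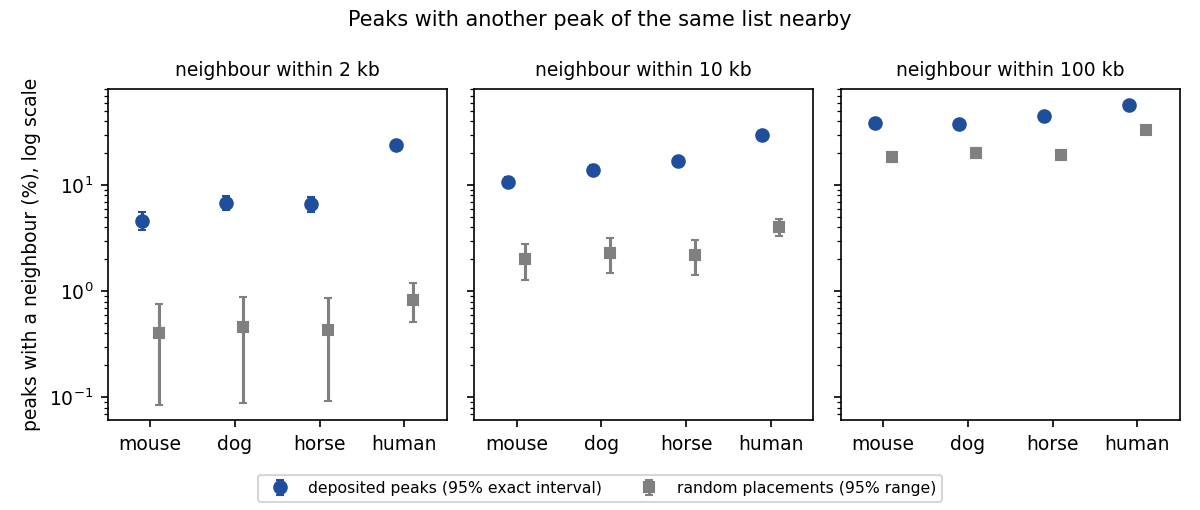
Share of peaks with another peak of the same list within 2, 10 or 100 kb, in percent on a log scale, for the 4 species, where blue points are the deposited peaks with exact 95% intervals and grey squares are the mean and central 95% range of 1000 random placements. Within 10 kb the deposited lists range from 10.7% in mouse to 29.6% in human, all above the placements.

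Dense bins, which hold 10 or more peaks in 1 Mb, numbered 5 in mouse, 8 in dog, 13 in horse and 35 in human, with 3.69%, 4.49%, 7.46% and 8.48% of the peaks. In mouse they were 3 adjacent bins on chromosome 4 and single bins on chromosome 7 (8 to 9 Mb) and chromosome 13 (65 to 66 Mb). The bin with the most peaks in the horse list, with 26, was on chromosome 1 from 162 to 163 Mb. In the dog list it was on chromosome 16 from 59 to 60 Mb, with 19 peaks, and in the human list on chromosome 19 from 42 to 43 Mb, with 21. By chromosome, human peaks were most frequent on chromosome 19, with 4.66 peaks per Mb up to the last peak, against 0.937 on the autosome with the fewest. The highest values were 2.29 per Mb in horse, on chromosome 12, and 2.64 per Mb in dog, on chromosome 26.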

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

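The human list was noted because it lies outside the measured samples: it holds 5260 peaks, and no sample of the series is human. The test without the dense bins in this part was chosen after a similar result had been seen. Human peaks had a neighbour within 2 kb more often than peaks of the other lists. A longer list alone does not account for this as far as random thinning can show, since thinned at random to 2357 peaks the human list still had 12.4% of peaks with such a neighbour (range of the central 95% of 100 draws 10.8 to 14.1%), above the 6.82% of the dog list. Thinning keeps weak and strong peaks alike, so a lower threshold in the human list stays open. The dense bins do not account for it either, since the share without them was 22.0%. Lists from several cell types joined into 1 list, with summits that differ by more than the peak width, could also give close pairs, and the sources used here do not say whether this was done; no biological explanation was tested.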

How the results depend on the processing

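The alternatives without dense bins, with length-matched lists, with named genes as background and with other reaches for microRNA genes were chosen after the data were seen. Of 126 alternative values, 120 kept their direction and their side of the threshold or, for counts and shares with no test, stayed within a preset margin. That margin takes in the 8 chromosomes off their share without the dense bins. The 120 include the peak number of each list, which could not change because no peaks overlapped and all lay on placed chromosomes. They also include control lists that passed in no setting, so 120 of 126 is not a measure of how robust the results are. An odds ratio that had not passed its test changed side of 1 for fibroblast markers, from 0.426 to 1.2 by the nearest gene end, and for peaks inside a gene span, from 1.04 to 0.959 with protein-coding genes only; neither passed the test there. The number of mouse chromosomes off their share, 11 against annotated length, was 5 when protein-coding genes set the expectation. The list of neurotrophins and growth factor signalling, with an odds ratio of 8.68, fell to 2.24 (adjusted p = 0.33, Fisher's exact test, with a range of 0.000181 to 1 over its alternatives) when only gene ends within 10 kb counted and to 0 when only ends within 1 kb counted, where none of its 17 genes had a peak. Against random lists of the genes nearest in length its count was 2.33 times their median (adjusted permutation p = 0.0534); its genes are long (median 183 kb, against 17.2 kb for all protein-coding genes), and the cause was not tested further. The other 7 neuronal lists that passed did so under each of these alternatives, which leave out the sign test against moved windows, where 3 of the 7 did not pass (synaptic vesicle, cytoskeleton and adhesion, synthesis and transport), and the odds ratio of the 9 lists together ranged from 13.3 (gene ends within 10 kb) to 20.2 (gene ends within 1 kb). Leaving out each replicate in turn was not possible because the lists hold no value per replicate. No paired analysis was possible because each species has 1 list for both replicates. Not run were the alternatives with a stricter score threshold, since peaks carry no score, and those on motif classes, motif spacing, sequence context and shared targets, which need sequences or annotations not used here. Depth is unknown, so a gene without a peak is one without a call at the authors' threshold, not one without binding.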

Other observations

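The tests of gene families, gene classes, length-matched lists, dog runs and lists without the dense bins were chosen after the data were seen. Gene families named by a shared symbol stem with at least 8 members were compared with all other protein-coding genes. Of 375 families, 7 had more genes with a mouse peak and 2 had fewer (Fisher's exact test, adjusted over families). The family tests took no account of gene length, and genes with a peak were longer (median 36.2 kb, against 17.2 kb for all protein-coding genes). Of the Cacna family of calcium channel subunits 9 of 14 genes had a peak (odds ratio 22.4, adjusted exact p = 1.28e-05), among them Cacna1d and Cacna2d2, which are in no fixed list. The Kcnh potassium channels (5 of 8 genes), the Grm metabotropic glutamate receptors (5 of 8), the Syt synaptotagmins (7 of 17), the Dock guanine exchange factors (6 of 11) and the Cdh cadherins (7 of 23) were also above other genes. Outside the fixed lists the counts were 5 of 9 for Cacna, 3 of 6 for Kcnh, 1 of 4 for Grm and 4 of 12 for Syt, so these families in part restate the lists, whereas no Dock or Cdh gene is in a list. Windows moved by 200 kb met 4 Cacna, 2 Kcnh, 4 Grm, 1 Syt, 3 Dock and 6 Cdh genes. The Grm and Cdh counts thus stand 1 gene above the moved windows. Such windows can stay inside genes longer than 200 kb (median length 318.2 kb for Grm and 257.7 kb for Dock). The median for Cdh was 147.7 kb, so this can concern only its longer members. The comparison with moved windows therefore cannot tell whether Grm and Dock stand at or above background, and it did not place Cdh above background. All 12 Pcdha protocadherin genes were counted through 1 peak, because their annotated spans overlap. Within 1 kb of an annotated end, a peak lay at 1 Kcnh, 2 Grm and 2 Syt genes and at 0 Cacna, 0 Dock and 0 Cdh genes. Olfactory receptor genes (Olfr, 14 of 1110) and vomeronasal receptor genes (Vmn, 8 of 355) had peaks less often than other genes, and moved windows met 12 and 11 of them. Genes of these 2 families are short (median length 0.95 and 0.963 kb), so their low counts cannot be told apart from an effect of length.

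Outside the dense bins, the protein-coding genes with the most mouse peaks were Dpp6, an auxiliary subunit of potassium channels, with 8 peaks, Rbfox3, which encodes the neuronal marker NeuN, with 7, and Camta1, also with 7. Asic2, an acid-sensing ion channel, and Atp2b2, a plasma membrane calcium pump, had 5 each. Dpp6 spans 910 kb, and Asic2 spans 1088 kb. Among the gene classes, 53 of 1228 microRNA genes had a peak and 31 had a window moved by 200 kb (odds ratio 1.74, adjusted p = 0.115, Fisher's exact test). That test took the 2 counts as independent although both are over the same genes.

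The excess of peaks at neuronal genes might come from their length, their position or the dense bins. Against 10000 random lists matched on decile of gene length, 126 neuronal genes with a peak compared with a median of 24 and a highest count of 42 (permutation p = 0.0002, two-sided, the smallest they can give). The longest decile has no upper bound, and with each member drawn from the 50 genes nearest in length the median was 27 and the highest count 45 at the same p, which argues against length as the whole cause. Windows moved by 200 kb gave an odds ratio of 3.41 against 16.3 for the peaks, so position or length may account for a part. Without the dense bins the odds ratio was 16.2. The choice of list members, which did not leave out genes already reported as NRSF targets, was not tested. The peaks are the authors' calls from NRSF immunoprecipitation, so they bear on its presence at these genes. Direct contact of NRSF through its DNA element remains a hypothesis, since the binding motif was not searched for under the peaks. The list of neurotrophins and growth factor signalling, at 7 genes with peaks and with moved windows, is open.

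The 5 dense bins of the mouse list may reflect multi-copy sequence, on which reads can be placed in the wrong copy. A median of 80.8% of their annotated genes were pseudogenes or numbered gene models, compared with 57.1% in the 1210 other bins with a peak (permutation test, one-sided, p = 0.0209). Of these 5 bins 3 are adjacent, so they are not independent. Zfp zinc-finger genes lay mainly in the block on chromosome 4, with 9, 5 and 2 in its bins, against 1 in the bin on chromosome 13 and 0 in that on chromosome 7, and Zfp978 and Zfp993 had 11 peaks each. Over the genome 38 of 397 Zfp genes had a peak (adjusted exact p = 0.764 against other genes), and 25 had one without the peaks in dense bins. Windows moved by 200 kb met 32 Zfp genes. The block spans 145 to 148 Mb, so moved windows can land on its Zfp genes again, and the 32 are not an independent background. Groups of neuronal targets as the source cannot be told apart from chance with so few bins: 1 of the 5 held a gene of the neuronal lists (Nppb, at the edge of the block), compared with 14.2% of the other bins (Fisher's exact test, p = 0.537). Binding at the zinc-finger genes themselves stays open, because no sequence or read depth was examined.

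The dog list alone held runs of at least 8 peaks whose starts were at most 5 kb apart. There were 4 such runs with 37 peaks, on chromosome 6 (43063350 to 43082025), chromosome 27 (13150525 to 13165775) and chromosome 26 (28875605 to 28884735 and 31268295 to 31283730), and none in the mouse, horse or human list. Chromosome 26 stood at 2.64 peaks per Mb, and at 2.23 without its runs, above the highest of the other 38 dog chromosomes (1.75). Its peaks fell in 69.2% of its 1 Mb bins, compared with a median of 53.6% and a highest value of 81.4% on the others. Copy number, multi-copy sequence and gene number were not examined in dog. The runs and the chromosome 26 value therefore cannot be read as a difference in binding.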
